A study of Arabidopsis lyrata subsp. lyrata with 18 samples.

How the data were processed

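Total RNA from shoots of 6-week-old soil-grown A. lyrata ssp. lyrata plants was extracted with Trizol and a column kit and labelled with Cy3, per the labels. Plants were flooded with 250 mM NaCl, 500 mM NaCl or water and harvested at 3 h and 27 h, 24 h apart, which gives 6 groups with 3 arrays each. For the higher dose a characteristics tag reads 250 mM, but the title says only high and the source name 500 mM, which was used. Per the file headers, the authors scanned 18 single-colour arrays of 1 Agilent design, and Feature Extraction wrote for each spot a background-subtracted, spatially detrended intensity that is not scaled between arrays. Per the file headers, the median pixel intensity of each spot and of its local background is unscaled too, and other columns hold flags that are 0 or 1. The deposited value table is in log2 units: checked against the scanner values, it is the log2 signal relative to the 75th percentile of its array, with each probe centred on its median over the 18 arrays, and the array medians of that table run from -0.438 to 0.446.

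Each array has 62976 spots, 1319 of them controls. Spots marked as outliers were left out, which removed all values of a probe on an array in 33 cases, and replicate spots of a probe were averaged on the log2 scale. The 32863 probes stand for 32386 gene models, 477 of which have 2 probes. The log2 processed intensity was reduced by the log2 75th percentile of its array. A probe was kept if it was well above background on all 3 arrays of at least 1 group, and the brightest probe stood for a gene model, which left 23415 models. No spot was saturated, and the signal range and limit on precision are given with the results.

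Group means were fitted with limma 3.58.1 in R 4.3.3 (with statmod 1.5.0 and version 1.17.8 of data.table) over all 18 arrays, with 12 residual degrees of freedom and no block, and the comparisons were salt against water at each harvest, 500 mM against 250 mM at each harvest, the change of each salt effect between harvests, and the harvests in watered plants. A model was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all models tested and an absolute log2 difference of at least 1. The 24 gene lists, with 430 entries of which 273 were on the array by code and 263 were measured, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over 144 tests of 24 lists in 6 comparisons. With the preset correlation 72 tests were called, 59 upward and 13 downward. With an estimated correlation 0 were called by camera, while 44 of the 144 tests had an unadjusted p under 0.05, and with fry 107 were called. Where a group was not well above background on any array, a lower bound of the fold against the background level is given as "at least".

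Genes were named only by the A. thaliana code in the name of the gene model, and symbols come from the fixed lists or general knowledge. No column gives symbols, so the code was taken as a name of its own. Of the models on the array 12409 carry a code. Named were the 10 largest rises and 10 largest falls in each comparison of salt with water and the 5 largest of each in the others, if called, above background on every array compared and, except for changes between harvests, without overlap of the arrays. Added were up to 4 members of each list with the smallest adjusted p, members needed to state a count, and 8 salt markers. Some list members were named after their values were seen: in the comparisons with water these are SOT17 and members named as falling or rising against the rest of their list, such as PIP2;1, TIP1;1, AOC2, LOX2, VSP2, RD22, P5CDH, RS4, FSD1, BAG6, ICS1, ALD1, WRKY70, PRR3, GRP7, CHI, CHS, KAT1, AKT2, CBL10, EXPA11 and IAA19, with SAG12, LHY, JUB1, AHG1, MYB29, GAPA1, PIP2;2, CYP79B2, CYP79B3, CYP83A1 and LHCB1.4.

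The lists, comparisons, thresholds and most alternatives were fixed before the data were examined. Those alternatives were the deposited value table, background correction by normexp with an offset of 50, quantile normalization, median centring, no filter on dim probes, a filter on all 18 arrays, the mean over probes, slide as a fixed or random block, a replicate block, fits within a slide or on the compared arrays alone, array weights, eBayes with trend and robust settings, no fold threshold, an adjusted p under 0.01, and leaving out each array. Normexp had been planned on mean signals and was run on median signals and median backgrounds. Array brightness as a covariate, scaling to 6 spike-in probes, the within-slide fits of single genes and lists, leaving out the 2 water arrays that share a slide with no salt array, dividing the water arrays between the doses, and exchanging the 2 water arrays that share a slide with the salt arrays of 3 h were chosen after the data were seen. The calls were tested on simulated data with 67, 67 and 66 of 23415 genes changed by a log2 of 1, 2 and 3. The fit recovered 34.3%, 85.1% and 97% of them with 3 false calls. Recovery where many more genes change, as in most real comparisons, was not simulated. With a simulated difference of the slide that holds water arrays alone, 98 false calls arose without a block and 9 with slide as a block. In simulated lists camera called 1 of 1 shifted list and 0 of the unshifted, which does not test the preset correlation for real lists. A table pairing RefSeq accessions with symbols was not used, as nothing links it to the gene models.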

Results

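Shoots of Arabidopsis lyrata ssp. lyrata, a perennial relative of A. thaliana, were profiled on 18 single-colour oligonucleotide arrays. The plants were 6 weeks old and grew in soil, and they received 250 mM NaCl, 500 mM NaCl or water and were harvested 3 h or 27 h later. The 2 harvests and 3 treatments make 6 groups with 3 arrays each. The 75th percentile of the probe signal ran from 477 to 2932 fluorescence units per array, and 59.9% to 74.7% of the probes lay well above background. The number of arrays limits the precision of each comparison. The arrays measured 23415 gene models above background in at least 1 group, and genes are named through the A. thaliana locus code that 38.3% of the models on the array carry. Gene values are log2 differences with the standard error of the fit, from 3 arrays in each group. A gene is said to have risen or fallen only where the adjusted p was under 0.05 and the difference at least 1 on the log2 scale. Each value is relative to the 75th percentile of its array, so it gives change against the bulk of the shoot transcripts. Where a group lay above background on 1 of its 3 arrays the fold is the fitted one, and its standard error does not cover the nearness to background. Where the largest changes are named, they are those among genes with a code that lay above background on every array compared. The p-values measure the spread between these 18 samples, since the labels do not say whether replicates were separate plants.

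The first principal component held 76.2% of the variance between arrays and placed all 6 water arrays between -123.6 and -149.6, the 250 mM arrays at 3 h between -98.4 and -130.8, the 500 mM arrays at 3 h between -7.2 and 27.9, the 250 mM arrays at 27 h between 106.3 and 111.4 and the 500 mM arrays at 27 h between 260.3 and 271.3. The second component held 11.2%. Correlations across genes between replicate arrays of a group lay between 0.971 and 0.995. Genes are not independent replicates in such a correlation.

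**Figure D1:**
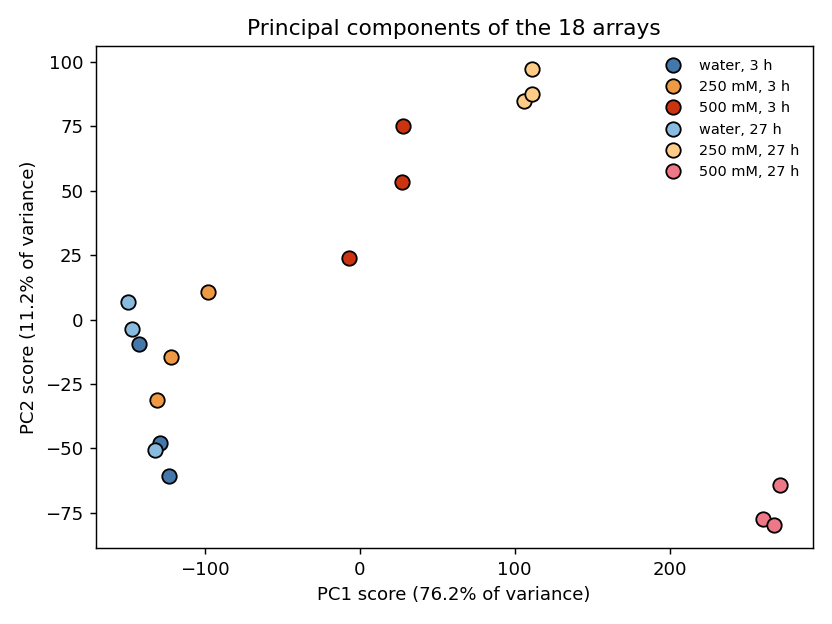
Scores of the 18 arrays on the first and second principal components of the log2 levels, with the percent of the variance in the axis labels and 1 point per array. The water arrays and the 250 mM arrays of 3 h lie at the left, the 500 mM arrays of 27 h at the right.

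Between salt and water 167 gene models differed at 250 mM and 3 h, 6228 at 500 mM and 3 h, 10202 at 250 mM and 27 h and 14057 at 500 mM and 27 h. The first of these counts was 63 with slide as a block and 70 to 416 on leaving out an array. In watered plants 7 models differed between the harvests. Among all models tested, the 3 salt arrays lay entirely above or below the 3 water arrays for 17.3%, 57.3%, 70.5% and 80.03% of them in the same order, where chance gives 10%.

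**Figure D2:**
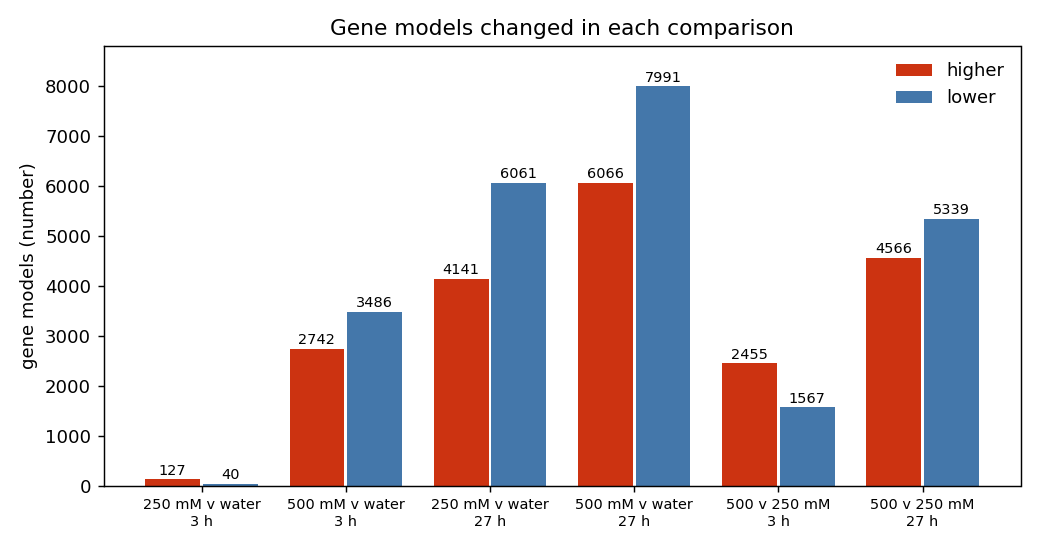
Number of gene models called higher (red) and lower (blue) in each of 6 comparisons, as bars from 0 with the count above each bar. The comparison of 250 mM with water at 3 h has 127 higher and 40 lower, and that of 500 mM with water at 27 h has 6066 higher and 7991 lower. With scaling to the spike-in probes 5.28% of the models changed at 250 mM and 3 h, 18.6% at 500 mM and 3 h and 95.3% at 250 mM and 27 h were higher.

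Of the 8 genes chosen as salt response markers, 6 could be matched by locus code. NCED3 (AT3G14440), the carotenoid-cleaving enzyme that limits abscisic acid synthesis in dehydrated plants, had a log2 level of 0.85 ± 0.26 (SD, n = 3) in water at 3 h. It reached 2.33 ± 0.67 at 250 mM and 6.4 ± 0.23 at 500 mM. At 27 h its level was 0.76 ± 0.40 in water, 5.46 ± 0.13 at 250 mM and 6.36 ± 0.12 at 500 mM. RD29B (AT5G52300), a dehydration marker driven by abscisic acid, rose by 2.22 ± 0.43 and 5.20 ± 0.43 at 3 h and by 5.89 ± 0.43 and 4.58 ± 0.43 at 27 h for 250 and 500 mM. The dehydrin RAB18 (AT5G66400) differed by 0.69 and 0.96 at 3 h, which did not reach the threshold, and rose by 2.15 and 3.56 at 27 h. P5CS1 (AT2G39800), the enzyme that commits glutamate to proline, differed by 0.79 at 250 mM and 3 h and then rose by 1.55 at 500 mM and 3 h, 2.48 at 250 mM and 27 h and 1.1 at 500 mM and 27 h. The plasma membrane sodium/proton exchanger SOS1 (AT2G01980) differed by -0.04 and 0.12 at 3 h, rose by 1.44 ± 0.34 at 250 mM and 27 h, and differed by -0.65 ± 0.34 at 500 mM and 27 h. The sodium transporter HKT1 (AT4G10310) differed by -0.03 and -0.94 at 3 h, the latter -1.37 and past the threshold with spike-in scaling, and was lower by the test at 27 h, with -1.66 ± 0.15 at 250 mM and -2.17 ± 0.15 at 500 mM. With arrays scaled to spike-in probes the HKT1 difference at 250 mM and 27 h was -0.18 and no longer passed, and with array brightness as a covariate that of SOS1 was 0.38 and did not pass, as for other genes named with that comparison. P5CS1 at 500 mM and 27 h was 0.87 and did not pass with quantile normalization. RD29A and NHX1 were not found by code.

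**Figure D3:**
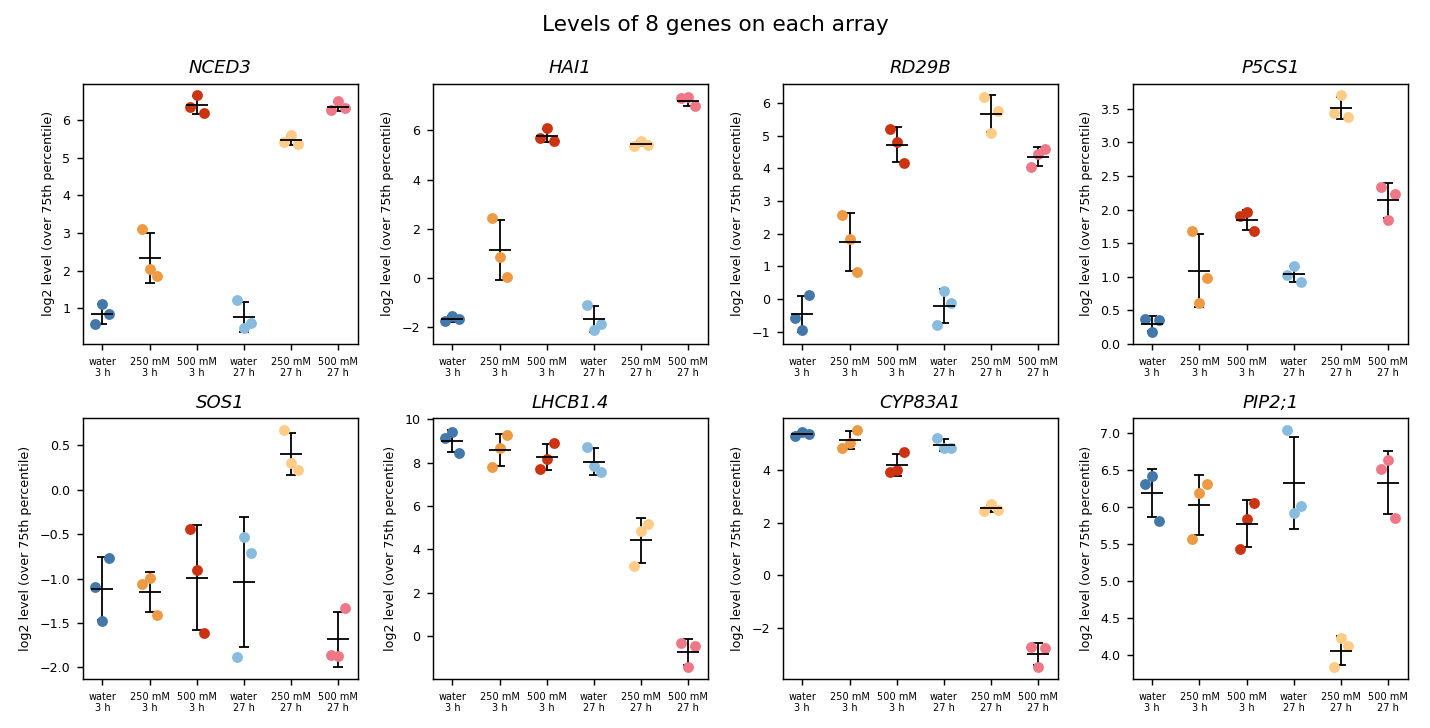
Log2 level over the array's 75th percentile of 8 genes on each array, by treatment and harvest. Points are arrays, the bar is the mean of 3 arrays and the whiskers are 1 SD. NCED3 has a mean of 0.85 in water and 6.4 at 500 mM at 3 h, and LHCB1.4 has a mean of 8.05 in water and -0.74 at 500 mM at 27 h.

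The comparison of 250 mM NaCl with water at 3 h asked which transcripts a moderate salt dose moved within the first hours. The phosphatases HAI1 (AT5G59220, 2.78 ± 0.42) and HAI2 (AT1G07430, 2.17 ± 0.29), which damp abscisic acid signalling, rose together with the NAC factors RD26 (AT4G27410, 2.40 ± 0.33) and ANAC019 (AT1G52890, 2.01 ± 0.43), the ubiquitin ligase PUB19 (AT1G60190, 2.40 ± 0.39), the sulfotransferase SOT12 (AT2G03760, 2.03 ± 0.39) and RD29B. The largest rises were AT1G07135 (3.43 ± 0.27, adjusted p = 1.1e-05) and AT1G67856 (3.05 ± 0.24), and AT5G51440 rose by 1.97. The galactinol synthase GOLS2 (AT1G56600), above background on 1 of the 3 water arrays, rose by 3.80 ± 0.67. Only 6 falls met the rule for named genes, and they were smaller: the cytokinin response regulator ARR6 (AT5G62920, -1.76 ± 0.40), the wall enzyme XTH33 (AT1G10550, -1.5), AT4G21870 (-1.42), the receptor kinase CRK30 (AT4G11460, -1.33), SIB1 (AT3G56710, -1.05) and ERF107 (AT5G61590, -1.04). In a fit with slide as a block these 6 falls, at -1.54, -1.42, -1.09, -1.43, -0.80 and -0.84 in the same order, did not pass. Neither did the rises of HAI1 (2.80 in that fit), HAI2 (1.80), RD26 (2.41), ANAC019 (1.86), PUB19 (2.45), SOT12 (2.35), RD29B (1.62), AT5G51440 (1.87) and GOLS2 (2.60). The standard errors of the calls lost at 250 mM and 3 h ran from 0.21 to 0.67 without the block and from 0.27 to 0.90 with it. The blocked fit rests on 1 of the 3 water arrays, since the other 2 lay alone on a slide, and calls can be lost through that alone.

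Among the fixed lists, 7 of 21 measured stress transcription factors rose at 250 mM and 3 h, among them ZAT10 (AT1G27730, 1.90 ± 0.29), ANAC055 (AT3G15500, 1.75) and MYB2 (AT2G47190), which was at least 3.08-fold higher than the background level of the water arrays. The list's median was 1.16 (camera adjusted p = 8.94e-12, adjusted p = 0.111 with an estimated correlation). Of 11 abscisic acid signalling genes 3 rose, the phosphatases HAI1 and HAI2 and the bZIP factor ABF3 (AT4G34000, 1.35), with a camera adjusted p of 1.45e-07 and an adjusted p of 0.111 with an estimated correlation. In the list of abscisic acid synthesis and breakdown NCED3 rose (camera adjusted p = 0.00552, adjusted p = 0.111 with an estimated correlation), among 10 late-embryogenesis and dehydration genes RD29B did (camera adjusted p = 0.000137, adjusted p = 0.111 with an estimated correlation), and among 12 proline and raffinose genes GOLS2 did (camera adjusted p = 0.00019, adjusted p = 0.135 with an estimated correlation). Of 14 heat shock genes 1 rose, HSFA6B (AT3G22830), at least 2.17-fold above background (camera adjusted p = 0.0149, adjusted p = 0.339 with an estimated correlation). Of the 3 measured root markers FRO2 (AT1G01580), a ferric chelate reductase, rose by 1.84 ± 0.27, while CASP1 (AT2G36100) differed by 0.65 and TIP2;3 (AT5G47450) by -0.09 (camera adjusted p = 0.00937, adjusted p = 0.127 with an estimated correlation). No member of 5 further lists called higher by camera passed alone: the jasmonate list had a median of 0.40 (adjusted p = 7.48e-05, and 0.259 as the adjusted p with an estimated correlation), the flavonoid list 0.38, oxidative stress 0.32, reference genes 0.22 and senescence 0.19. With an estimated correlation the adjusted p of these last 4 lists was 0.418, 0.212, 0.232 and 0.178. Glucosinolate synthesis (median -0.44, camera adjusted p = 0.00153) and cell wall expansion and auxin (median -0.36, camera adjusted p = 0.0244) were the lists called lower, with an adjusted p of 0.111 and 0.494 with an estimated correlation. The 33 photosynthesis genes had a median of -0.23, and 0 of them reached an unadjusted p under 0.05 in limma. Adjusted over the list alone, 10 stress transcription factors and 1 senescence gene rose, and 1 abscisic acid receptor, 1 defence gene, 2 wall genes and 2 glucosinolate genes fell, with the other counts as given. Blocked by slide, ANAC055 (1.39), MYB2 (1.79), ABF3 (1.11), NCED3 (1.47), HSFA6B (1.31) and FRO2 (1.47) did not pass, while 2 of the 21 stress transcription factors did. Camera then no longer called the lists of senescence, oxidative stress, heat shock, wall and auxin, flavonoid, reference and root marker genes. With scaling to spike-in probes 0 of 21 stress transcription factors, 1 of 11 abscisic acid signalling genes and 0 genes of the abscisic acid synthesis, dehydration, heat shock and root lists were higher. The median of the stress transcription factors was then 0.40, and the medians of the other lists called higher lay below 0, from -0.11 to -0.57. ANAC055 lay above background on 1 of the 3 water arrays.

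In all, 127 models rose and 40 fell at 250 mM and 3 h, with a median of -0.078 over all 23415 models tested, and 3344 models had an unadjusted p under 0.05. Of the 3 water arrays of this harvest 2 lay alone on a slide, and with slide as a block 63 models passed (56 higher and 7 lower, 45 of them shared with the 167), while 1 passed within the slide that held the third water array. That slide sets 3 salt arrays against 1 water array, and the spread there comes from the salt groups. The count was 70, 77 and 416 without water replicates 1, 2 and 3 in turn, and 83 and 93 without 250 mM replicates 1 and 2. In all, 15 named rises and 6 named falls did not pass with slide as a block. The spike-in signal was 9.88 and 9.80 log2 units on the 2 water arrays alone on a slide and 11.62 on the third. Spike-in scaling at 3 h therefore carries a slide difference. With scaling to spike-in probes 16 models were higher and 287 lower, with a median of -0.835 over all models. Of the named rises 14 did not pass then, and HAI1, GOLS2, AT1G07135 and AT1G67856 did. Normexp correction ended 12 named calls, the rises of ABF3 (1.22), ANAC019 (1.24), ANAC055 (0.25), AT5G51440 (1.33), GOLS2 (1.96), HSFA6B (0.07), MYB2 (0.35) and SOT12 (1.48) and the falls of ARR6, ERF107, SIB1 and XTH33. Without water replicate 1 the calls of ABF3, ANAC019, GOLS2, HSFA6B, MYB2, NCED3, RD29B and SOT12 and all named falls but that of AT4G21870 did not pass, 13 in all, and 10, 8 and 9 of these were lost without water replicate 2 and 250 mM replicates 1 and 2. With brightness as a covariate ERF107 and SIB1 (both -0.98) were lost, with median centring these and ARR6, with quantile normalization ABF3 and SIB1, and with a replicate block ABF3, ANAC019 and SIB1.

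The comparison of 500 mM NaCl with water at 3 h asked what the high dose did in the same time. ERF11 (AT1G28370) rose by 7.67 ± 0.33, ORA47 (AT1G74930), an AP2/ERF factor of jasmonate synthesis, by 8.33 ± 0.33, the cytokinin response factor CRF6 (AT3G61630) by 8.09 ± 0.39, and the calmodulin-like CML38 (AT1G76650) by 8.06 ± 0.35. AT1G07135 (8.80 ± 0.27), AT5G24640 (8.68), AT1G67856 (8.20), SOT12 (8.08), AT5G51440 (8.01) and AT1G76600 (7.90) were the other largest rises. The largest falls were AT2G45180 (-4.58 ± 0.66), the arabinogalactan protein FLA9 (AT1G03870, -4.46 ± 0.59), the growth-promoting factor HBI1 (AT2G18300, -3.22), AT5G62360 (-3.18), the glucosinolate regulator MYB29 (AT5G07690, -3.13 ± 0.26), the chloroplast transporter BAT5 (AT4G12030, -3.02), PAR2 (AT3G58850, -2.96), CRK30 (-2.95), the abscisic acid receptor PYL6 (AT2G40330, -2.94 ± 0.39) and BZIP3 (AT5G15830, -2.92).

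Of 21 stress transcription factors 20 rose at 500 mM and 3 h, with a median of 6.56, and JUB1 (AT2G43000, -0.19), which lay above background on 1 of the 3 salt arrays and on 0 of the 3 water arrays, did not pass. The ethylene-response factors ERF105 (AT5G51190, 8.45) and ERF104 (AT5G61600, 7.12) and ZAT10 (7.17) were among them (camera adjusted p = 3.34e-19, adjusted p = 0.111 with an estimated correlation). Of 17 jasmonate genes 13 rose, including the repressors JAZ1 (AT1G19180, 5.72 ± 0.34), JAZ7 (AT2G34600, 6.87) and JAZ10 (AT5G13220, 3.79) and the synthesis enzyme AOC3 (AT3G25780, 2.81), with a camera adjusted p of 3.39e-10 and an adjusted p of 0.127 with an estimated correlation. Of 11 abscisic acid signalling genes 6 rose, led by HAI1 (7.44 ± 0.42), HAI2 (6.20) and AHG3 (AT3G11410, 3.36), with a camera adjusted p of 4.41e-05 and an adjusted p of 0.111 with an estimated correlation. In abscisic acid synthesis and breakdown 4 of 11 rose, NCED3 (5.55 ± 0.27), NCED2 (AT4G18350, 3.19), NCED5 (AT1G30100, 2.53) and the breakdown enzyme CYP707A1 (AT4G19230, 1.97), with a camera adjusted p of 0.00501 and an adjusted p of 0.111 with an estimated correlation. The embryogenesis protein gene LEA7 (AT1G52690) was at least 41.7-fold higher, and ERD10 (AT1G20450, 2.98) and the lipid transfer protein gene LTP3 (AT5G59320, 3.67) also rose, among 6 of 10 in their list (camera adjusted p = 1.75e-05, adjusted p = 0.111 with an estimated correlation). Of 12 proline and raffinose genes 7 rose, among them GOLS2 (9.22), GOLS1 (AT2G47180, 2.76) and the proline transporter PROT2 (AT3G55740, 1.67), with a camera adjusted p of 0.000339 and an adjusted p of 0.156 with an estimated correlation.

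Defence and redox genes rose as well at 500 mM and 3 h. Of 10 salicylate and pathogen defence genes 7 rose, with CBP60G (AT5G26920, 5.55 ± 0.41) and the camalexin synthesis gene CYP71A13 (AT2G30770, 5.13) among them, and PAD3 (AT3G26830) at least 37-fold higher (camera adjusted p = 0.000636, adjusted p = 0.159 with an estimated correlation). Of 11 oxidative stress genes 7 rose, with the glucosyltransferase UGT74E2 (AT1G05680) at least 3000-fold higher, GSTF7 (AT1G02920) at 4.88, GSTF6 (AT1G02930) at 3.56 and the alternative oxidase AOX1A (AT3G22370) at 2.43 (camera adjusted p = 4.41e-05, adjusted p = 0.111 with an estimated correlation). Of 14 heat shock genes 9 rose, led by the heat shock factor HSFA2 (AT2G26150, 5.0), and HSFA6B was at least 24-fold higher (camera adjusted p = 0.000139, adjusted p = 0.159 with an estimated correlation). Of 8 ethylene genes 2 rose, ERF2 (AT5G47220, 2.81) and the synthase ACS8 (AT4G37770, 2.16), with a camera adjusted p of 0.0194 and an adjusted p of 0.112 with an estimated correlation. Of 10 senescence genes 3 rose, the NAC factors NAP (AT1G69490, 4.68) and ORE1 (AT5G39610, 3.22) and WRKY53 (AT4G23810, 1.83), with a camera adjusted p of 0.0194 and an adjusted p of 0.162 with an estimated correlation. Of 33 photosynthesis genes 2 fell, the antenna gene LHCB3 (AT5G54270, -1.03 ± 0.22) and GAPA1 (AT3G26650, -1.03 ± 0.37), and the list's median was -0.63 (camera adjusted p = 0.0246, adjusted p = 0.720 with an estimated correlation). Of 6 chlorophyll synthesis genes PORB (AT4G27440, -1.88) and GUN4 (AT3G59400, -1.82) fell (camera adjusted p = 0.0437, adjusted p = 0.411 with an estimated correlation).

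The other lists were not called by camera at 500 mM and 3 h. Of 13 ion transport genes 3 rose, among them the cation exchanger CHX17 (AT4G23700, 3.86 ± 0.44) and the anion channel SLAH3 (AT5G24030, 2.35), with an adjusted p of 0.214. Of 14 aquaporins 4 fell, among them the tonoplast TIP1;2 (AT3G26520, -1.81), and TIP2;2 (AT4G17340) rose by 2.79 (adjusted p = 0.880). Of 9 glucosinolate genes 4 fell, BAT5, MYB29, CYP83A1 (AT4G13770, -1.16) and SOT17 (AT1G18590, -1.99), and 3 rose, among them CYP79B3 (AT2G22330, 2.07), with an adjusted p of 0.936. Of 13 wall and auxin genes 3 rose, among them XTH18 (AT4G30280, 7.20) and XTH19 (AT4G30290, 4.54), and 3 fell, among them XTH16 (AT3G23730, -2.32) and XTH9 (AT4G03210, -2.02), so that the median of -0.52 and the mean of 0.26 differ in sign (adjusted p = 0.679). Of 4 cell cycle genes 3 fell, led by CYCA1;1 (AT1G44110, -1.99), with an adjusted p of 0.103. In the clock list LUX (AT3G46640, 2.40), FKF1 (AT1G68050, 1.42) and RVE1 (AT5G17300), at least 2.5-fold higher, rose and PRR3 (AT5G60100, -1.34) fell (adjusted p = 0.220), although RVE1 read -0.02 with background correction by normexp. Of 14 flavonoid genes 3 rose, the regulator PAP1 (AT1G56650, 1.34), F3H (AT3G51240, 1.08) and FLS1 (AT5G08640, 1.29), with a median of -0.45, a mean of -0.03 and an adjusted p of 0.484 upward. Of the reference genes UBQ10 (AT4G05320) rose by 1.16, of the root markers FRO2 by 3.22, and the flower markers SEP3 (AT1G24260, -0.62) and PI (AT5G20240, -0.93) did not pass. Adjusted over the list alone, 1 defence gene also fell, and the other counts of this comparison were the same.

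In all, 2742 models rose and 3486 fell at 500 mM and 3 h, 44.0% of the changed ones upward, but the median of all models was -0.353, and relative to it 3608 were higher and 1509 lower (70.5% upward), and with quantile normalization 53.5% of the changed models were higher. With slide as a block 5534 models passed, and 4548 within the slide that held all salt arrays of this harvest and 1 water array. With normexp correction 3850 models passed. With slide as a block CDKB1;1 (AT3G54180, -1.07), F3H (0.68), GAPA1 (-0.60), LHCB3 (-0.91) and UBQ10 (0.97) did not pass. In that fit 1 of 14 aquaporins was lower and the photosynthesis list was not called. With scaling to spike-in probes 1760 models were higher and 7714 lower, with a median of -0.791 over all models. P5CS1 (1.11), F3H (0.64), FLS1 (0.85), PAP1 (0.90), FKF1 (0.98), RVE1 (1.3) and UBQ10 (0.72) did not pass with it. Lower were then 19 of 33 photosynthesis, 4 of 6 chlorophyll synthesis, 7 of 14 aquaporin, 6 of 13 wall and auxin, 3 of 13 ion transport, 3 of 11 clock and 2 of 14 flavonoid genes, and 1 clock gene, 1 glucosinolate gene and 4 of 10 dehydration genes were higher. The medians of the abscisic acid synthesis (-0.04), senescence (-0.05) and ethylene (-0.03) lists turned below 0, and camera no longer called the chlorophyll synthesis and ethylene lists. GOLS2, CYP71A13 and CHX17 lay above background on 1 of the 3 water arrays. Normexp also ended the calls of CYP707A1 (0.76), WRKY53 (0.87), F3H (0.48), GAPA1 (-0.98) and LHCB3 (-0.99), median centring those of GAPA1 and LHCB3 (both -0.99), and brightness as a covariate (-0.66) and quantile normalization (-0.62) that of GAPA1. Without water replicate 1 or 500 mM replicate 1 F3H (0.91 and 0.98), GAPA1 (-0.99 and -0.76) and LHCB3 (both -0.98) did not pass, nor did GAPA1 without water replicate 2 (-0.86) or 500 mM replicate 2 (-1.02).

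The comparison of 250 mM NaCl with water at 27 h asked how the moderate dose stood a day later. AT1G56060 rose by 11.17 ± 0.38, the glutathione transferase GSTU9 (AT5G62480) by 10.63 ± 0.49, the zinc finger factor ZAT7 (AT3G46090) by 9.94 ± 0.38, GOLS2 by 9.87 ± 0.67, the cell death regulator BAP2 (AT2G45760) by 9.78, the wall enzyme XTH18 by 9.61 and the kinase MAPKKK18 (AT1G05100) by 9.34. AT1G67856 (9.59), AT1G07135 (9.58) and AT3G10930 (9.50) completed the 10 largest. The largest falls were AT1G19960 (-5.80 ± 0.34), the expansin EXPB1 (AT2G20750, -5.64 ± 0.31), XTH31 (AT3G44990, -5.51 ± 0.43), AT2G21650 (-5.41), AT3G55240 (-4.97), CRK30 (-4.66), AT5G25090 (-4.62), AT1G75250 (-4.60), the antenna gene LHCB4.2 (AT3G08940, -4.47 ± 0.29) and AT1G68238 (-4.31).

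All 33 measured photosynthesis genes fell at 250 mM and 27 h relative to the array's 75th percentile, with a median of -2.08. With scaling to spike-in probes 9 of the 33 passed as lower and the median was -0.60. PSAF (AT1G31330) of photosystem I (-4.02 ± 0.17), PSAD1 (AT4G02770, -2.90) and PSBQ2 (AT4G05180) of photosystem II (-2.73) were among the falls (camera adjusted p = 2.82e-08, adjusted p = 0.384 with an estimated correlation). Of 6 chlorophyll synthesis genes 4 fell, GUN4 (-3.08), PORB (-2.90), PORC (AT1G03630, -2.24) and PORA (AT5G54190, -2.22), of which PORA and PORC no longer passed with spike-in scaling (camera adjusted p = 0.0160, adjusted p = 0.333 with an estimated correlation). Of 10 senescence genes 8 rose, among them NAP (5.05), ORE1 (3.88), the sugar transporter SWEET15 (AT5G13170, 4.1) and the protease SAG12 (AT5G45890), at least 134-fold higher (camera adjusted p = 0.000133, adjusted p = 0.111 with an estimated correlation). All 4 cell cycle genes fell, CDKB1;1 (-3.03), CYCA1;1 (-2.61), CYCB1;1 (AT4G37490, -2.33) and CDKB2;1 (AT1G76540, -1.5), of which the last 2 did not pass with spike-in scaling (camera adjusted p = 0.0376, adjusted p = 0.183 with an estimated correlation).

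Of 14 aquaporins 10 fell at 250 mM and 27 h and TIP2;2 (2.28) rose. The plasma membrane aquaporin PIP2;1 (AT3G53420) read -2.26 ± 0.31, PIP1;3 (AT1G01620) -2.15, PIP1;5 (AT4G23400) -2.01 and the tonoplast TIP1;1 (AT2G36830) -1.91 (camera adjusted p = 0.0450, adjusted p = 0.628 with an estimated correlation). With spike-in scaling the aquaporin median moved from -1.49 to -0.01, and PIP2;1 (-0.78), PIP1;3 (-0.67), PIP1;5 (-0.53) and TIP1;1 (-0.43) did not pass. Of 11 clock genes 7 rose, among them RVE1 (6.14 ± 0.38), RVE8 (AT3G09600, 4.02) and LUX (3.21), with LHY (AT1G01060) at least 39.8-fold higher, and PRR3 (-1.58) and GRP7 (AT2G21660, -1.11) fell (camera adjusted p = 0.00305, adjusted p = 0.111 with an estimated correlation), although with spike-in scaling PRR3 read -0.09 and GRP7 0.37, and GRP7 read 0.16 with quantile normalization. Of 14 flavonoid genes 7 rose, including the regulator TT8 (AT4G09820, 3.18), F3H (3.14) and FLS1 (2.54), with a camera adjusted p of 0.0194 and an adjusted p of 0.535 with an estimated correlation.

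All 21 stress transcription factors rose at 250 mM and 27 h, with a median of 6.21, among them ERF104 (7.95) and ANAC055 (6.13), with a camera adjusted p of 4.42e-15 and an adjusted p of 0.111 with an estimated correlation. Of 11 abscisic acid signalling genes 8 rose, HAI1 by 7.12, HAI2 by 5.56 and AHG3 by 3.69 among them, and AHG1 (AT5G51760) read -1.18, or 0.30 with spike-in scaling (camera adjusted p = 0.000226, adjusted p = 0.127 with an estimated correlation). In synthesis and breakdown 5 of 11 rose, among them NCED3 (4.69) and NCED2 (3.95) and the breakdown genes CYP707A1 (2.34) and CYP707A4 (AT3G19270, 2.08), with a camera adjusted p of 0.0247 and an adjusted p of 0.159 with an estimated correlation. Of 10 embryogenesis and dehydration genes 9 rose, LEA7 by 9.68, LTP3 by 5.93 and COR15B (AT2G42530) by 2.37 among them (camera adjusted p = 5.36e-05, adjusted p = 0.111 with an estimated correlation). Of 12 proline and raffinose genes 8 rose, including the amylase BAM1 (AT3G23920, 3.83), and the proline-degrading P5CDH (AT5G62530) fell by 1.97, a change of -0.49 and not past the threshold with spike-in scaling (camera adjusted p = 0.00305, adjusted p = 0.199 with an estimated correlation). Of 11 oxidative stress genes 8 rose, UGT74E2 at least 8570-fold, GSTF7 by 4.85 and the catalase CAT2 (AT4G35090) by 4.84 (camera adjusted p = 0.00019, adjusted p = 0.111 with an estimated correlation). Of 14 heat shock genes 12 rose, HSFA6B by 5.70 and MBF1C (AT3G24500) by 4.35 among them (camera adjusted p = 1.36e-06, adjusted p = 0.111 with an estimated correlation). Of 10 defence genes 7 rose, including CBP60G (7.34), PAD3 (7.23) and CYP71A13 (6.86), and the salicylate synthase ICS1 (AT1G74710) read -1.31, or 0.17 with spike-in scaling (camera adjusted p = 0.00305, adjusted p = 0.199 with an estimated correlation).

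Of 17 jasmonate genes 11 rose at 250 mM and 27 h, among them JAZ1 (6.34), JAZ7 (6.0), LOX4 (AT1G72520, 4.41) and AOC3 (2.41). The lipoxygenase LOX2 (AT3G45140) fell by 2.46, a change of -0.98 that did not pass with spike-in scaling, and AOC2 (AT3G25770) read -1.30, or 0.18 with spike-in scaling (camera adjusted p = 0.000892, adjusted p = 0.347 with an estimated correlation). The remaining lists were not called by camera. Of 13 ion transport genes 4 rose, CHX17 (3.99), SLAH3 (2.62), CAX3 (AT3G51860, 2.26) and SOS1, and HKT1 and the calcium sensor CBL10 (AT4G33000, -1.18, or 0.30 with spike-in scaling) were lower, with an adjusted p of 0.343. Of 9 glucosinolate genes 2 rose, MYB51 (AT1G18570, 1.45) and CYP79B3 (1.69), and 5 were lower, among them BAT5 (-3.63), CYP83A1 (-2.41), MYB29 (-1.42) and SUR1 (AT2G20610, -1.24), of which MYB29 and SUR1 turned to 0.06 and 0.24 with spike-in scaling and CYP83A1 did not pass (adjusted p = 0.362). Of 13 wall and auxin genes XTH18 and XTH19 (6.32) rose and 6 were lower, among them XTH4 (AT2G06850, -2.97) and EXPA1 (AT1G69530, -1.27, or 0.21 with spike-in scaling), with a median of -0.95 (0.53 with spike-in scaling), a mean of 0.25 and an adjusted p of 0.759. Of 8 ethylene genes 3 rose, the synthase ACS7 (AT4G26200) at least 110-fold, ERF2 by 2.78 and EIN3 (AT3G20770) by 1.17, with a median of -0.03, a mean of 1.13 and an adjusted p of 0.295. PYL6 fell by 3.73 and PYL1 (AT5G46790) differed by -0.44, or 1.04 with spike-in scaling, the 2 abscisic acid receptors measured (adjusted p = 0.352). Among the reference genes UBQ10 rose by 1.5 while GAPC1 (AT3G04120, 0.71), SAND (AT2G28390, 0.36) and TIP41 (AT4G34270, -0.78) did not pass (adjusted p = 0.317). FRO2 rose by 3.03, and CASP1 (-1.71) and TIP2;3 (-1.1) were lower, of which CASP1 did not pass and TIP2;3 turned to 0.38 with spike-in scaling (adjusted p = 0.965). The flower marker SEP3 read -1.12, or 0.37 with spike-in scaling, and PI -0.10, or 1.38 with that scaling (adjusted p = 0.524). Adjusted over the list alone, the counts of both salt comparisons with water at 27 h were the same.

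In all, 4141 models rose and 6061 fell at 250 mM and 27 h, 40.6% upward, with a median of -0.291 over all models. Relative to that median 5023 were higher and 4278 lower (54.0% upward), and with scaling to spike-in probes 12857 were higher and 639 lower (95.3% upward), so the falls stated here are falls against the other transcripts of the same array. The 75th percentile stood 1.48 log2 units higher over the spike-ins at 250 mM than in water at this harvest (exact two-sided permutation p = 0.1, the smallest that 3 against 3 arrays allow). With spike-in scaling 2 of 6 chlorophyll synthesis, 2 of 4 cell cycle, 1 of 14 aquaporin, 1 of 13 wall and auxin and 1 of 9 glucosinolate genes were lower. Higher with it were 10 of 11 abscisic acid synthesis and breakdown, 9 of 13 ion transport, 13 of 14 flavonoid, 5 of 8 ethylene, 4 of 13 wall and auxin and 3 of 4 reference genes. In the fit with slide as a block 9747 models passed, and 9751 within the slide that held the salt arrays and 2 water arrays. In the blocked fit AHG1 (-0.68), AOC2 (-0.99), EIN3 (0.86), GRP7 (-0.97) and TIP2;3 (-0.98) did not pass. The lists of cell cycle and aquaporin genes were not called there. With array brightness as a covariate 12 calls did not pass, those of SOS1, EIN3 (0.36) and SAG12 (5.24) among the rises and of AHG1 (0.00), AOC2 (-1.11), CBL10 (-0.69), CDKB2;1 (-0.63), EXPA1 (-0.97), GRP7 (-0.63), TIP1;1 (-0.91), TIP2;3 (-0.77) and PIP2;2 (AT2G37170, -0.60), an aquaporin, among the falls. Without water replicate 1 the same 5 genes as in the blocked fit did not pass, nor did AOC2 (-0.74) without 250 mM replicate 1 and TIP2;3 (-0.99) without replicate 3. RVE1, CYP71A13, HSFA6B, LEA7 and PAD3 lay above background on 1 of the 3 water arrays at 27 h, and CASP1 on 1 of the 3 salt arrays.

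The comparison of 500 mM NaCl with water at 27 h asked how the high dose stood a day later. The largest rises were AT1G56060 (13.56 ± 0.38), GSTU9 (11.95 ± 0.49), ZAT7 (11.68 ± 0.38), AT3G10930 (11.63), ORA47 (11.45 ± 0.33), MAPKKK18 (11.30), XTH18 (11.16), AT5G64120 (11.08), AT1G07135 (11.05) and the blue copper protein BCB (AT5G20230, 11.04). The largest falls were AT2G45180 (-8.97 ± 0.66), LHCB1.4 (AT2G34430, -8.79 ± 0.52), which binds chlorophyll in the main antenna, the lipase LTL1 (AT3G04290, -8.05 ± 0.33), CYP83A1 of glucosinolate synthesis (-7.93 ± 0.24), AT3G55240 (-7.88), CYP96A12 (AT4G39510, -7.74), AT2G10940 (-7.44), AT2G29290 (-7.40), AT3G01440 (-7.36) and AT2G42690 (-7.22).

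All 33 photosynthesis genes fell at 500 mM and 27 h, with a median of -4.33 and of -3.77 with spike-in scaling. LHCB4.2 (-6.93), PSAF (-6.95 ± 0.17), PSBQ2 (-6.23) and LHCB5 (AT4G10340, -5.20) were among them (camera adjusted p = 7.97e-10, adjusted p = 0.333 with an estimated correlation). All 6 chlorophyll synthesis genes fell, including PORB (-6.81), GUN4 (-5.94) and PORC (-5.93), with a camera adjusted p of 0.00503 and an adjusted p of 0.259 with an estimated correlation. All 10 senescence genes rose, NAP by 6.58, SWEET15 by 6.25, ORE1 by 5.76, and SAG13 (AT2G29350) and SAG12 at least 216-fold and 144-fold (camera adjusted p = 0.000122, adjusted p = 0.111 with an estimated correlation). All 4 cell cycle genes fell, CYCA1;1 (-6.93) and CDKB1;1 (-5.6) among them, each above background on 1 of the 3 salt arrays, and CYCB1;1 at least 12.5-fold (camera adjusted p = 0.0365, adjusted p = 0.183 with an estimated correlation). Of 13 wall and auxin genes 9 fell, among them the expansins EXPA11 (AT1G20190, -7.17 ± 0.54) and EXPA1 (-2.64) and XTH9 (-4.51), while XTH18, XTH19 (7.82) and IAA19 (AT3G15540, 2.53) rose (camera adjusted p = 0.317). Of 9 glucosinolate genes 5 fell, including MYB29 (-6.14) and BAT5 (-5.71) beside CYP83A1, and 3 rose, including CYP79B3 (4.07) and CYP79B2 (AT4G39950, 2.76), with a camera adjusted p of 0.583.

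All 21 stress transcription factors rose at 500 mM and 27 h, with a median of 7.87, ANAC055 (9.58), ZAT10 (8.53) and WRKY6 (AT1G62300, 5.25) among them (camera adjusted p = 1.75e-10, adjusted p = 0.127 with an estimated correlation). Of 11 abscisic acid signalling genes 7 rose, HAI1 by 8.89 and AHG3 by 5.21 among them (camera adjusted p = 0.00112, adjusted p = 0.159 with an estimated correlation). In synthesis and breakdown 5 of 11 rose, including NCED2 (5.6), NCED3 (5.59) and CYP707A1 (3.38), and BG1 (AT1G52400), a glucosidase that frees abscisic acid from its conjugate, fell by 5.55 (camera adjusted p = 0.150). Of 10 embryogenesis and dehydration genes 9 rose, LEA7 by 12.75 and LTP3 by 5.53 among them, and RD22 (AT5G25610) fell by 1.80 (camera adjusted p = 0.00117, adjusted p = 0.135 with an estimated correlation). Of 12 proline and raffinose genes 9 rose, including GOLS2 (10.85), BAM1 (5.23) and PROT2 (4.0), and P5CDH (-2.33) and RS4 (AT4G01970, -1.22) fell (camera adjusted p = 0.0051, adjusted p = 0.228 with an estimated correlation). Of 17 jasmonate genes 14 rose, JAZ1 by 6.36, LOX4 by 5.76 and AOC2 by 2.56 among them, and LOX2 (-4.09) and the storage protein gene VSP2 (AT5G24770, -2.93) fell (camera adjusted p = 0.000537, adjusted p = 0.333 with an estimated correlation). Of 11 oxidative stress genes 7 rose, with GSTF7 at 5.51 and CAT2 at 4.86, and the iron superoxide dismutase FSD1 (AT4G25100) fell by 2.74 (camera adjusted p = 0.00567, adjusted p = 0.178 with an estimated correlation). Of 14 heat shock genes 12 rose, HSFA6B by 6.49 and ROF2 (AT5G48570) at least 127-fold among them, and BAG6 (AT2G46240) fell by 1.05 (camera adjusted p = 0.000133, adjusted p = 0.159 with an estimated correlation). Of 10 defence genes 8 rose, including CYP71A13 (9.89) and PAD3 (9.20), and WRKY70 (AT3G56400) fell by 1.16 (camera adjusted p = 0.00552, adjusted p = 0.228 with an estimated correlation).

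Of 11 clock genes 8 rose at 500 mM and 27 h, RVE1 by 7.44 and LUX by 5.4 among them and LHY at least 32.3-fold, and PRR3 (-4.22) and GRP7 (-2.24) fell (camera adjusted p = 0.0326, adjusted p = 0.159 with an estimated correlation, and 0.0520 by camera with spike-in scaling). Of 14 flavonoid genes 9 rose, including TT8 (3.97), and the entry enzymes CHI (AT3G55120, -1.34) and CHS (AT5G13930, -1.14) fell (camera adjusted p = 0.0480, adjusted p = 0.592 with an estimated correlation, and 0.0522 by camera with spike-in scaling). Of 13 ion transport genes 4 rose, among them CHX17 (6.46) and CAX3 (4.44), and 4 fell, HKT1, CBL10 (-1.73) and the potassium channels KAT1 (AT5G46240, -3.14 ± 0.45) and AKT2 (AT4G22200, -2.58 ± 0.18), with a median of -0.61, a mean of 0.26 and a camera adjusted p of 0.981. Of 14 aquaporins 5 fell, among them PIP2;8 (AT2G16850, -4.49) and PIP2;7 (AT4G35100, -3.42), and TIP2;2 (4.25) rose, with PIP2;1 at 0.01 ± 0.31 and a list median of -0.36, or 0.20 with spike-in scaling (camera adjusted p = 0.487). The ethylene synthesis gene ACS7 was at least 826-fold higher and ACS8 rose by 4.68, among 3 of 8 ethylene genes that rose (camera adjusted p = 0.0664, and 0.0474 with spike-in scaling). UBQ10 (1.68) and GAPC1 (1.48) rose among 4 reference genes (adjusted p = 0.305). FRO2 rose by 1.68 and CASP1 fell by 1.03 among the root markers, with a median of -0.22, a mean of 0.14 and an adjusted p of 0.862. The floral organ regulator PI rose by 7.16 ± 0.24 while SEP3 differed by -0.94, so the list of flower markers was not called (adjusted p = 0.565). PYL6 and PYL1 differed by -0.67 and -0.02 (adjusted p = 0.936).

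In all, 6066 models rose and 7991 fell at 500 mM and 27 h, 43.2% upward, with a median of -0.283 over all models. Relative to it 6917 were higher and 6839 lower, and with spike-in scaling 7877 were higher and 5646 lower (58.3% upward). With that scaling 5 of 8 ethylene genes were higher and 0 of 14 flavonoid genes lower. With slide as a block 14243 models passed, and 14254 within the slide of the salt arrays. In the blocked fit CASP1 (-0.86), CDKB2;1 (-0.99) and CHS (-0.78) did not pass and the cell cycle, clock and flavonoid lists were not called. Normexp ended the calls of BAG6 (-0.80), CASP1 (-0.50), CDKB2;1 (-0.94), RS4 (-0.79) and WRKY70 (-0.91), quantile normalization those of BAG6 (-0.74), CDKB2;1 (-0.93), P5CS1, RS4 (-0.96) and WRKY70 (-0.91), median centring those of BAG6 (-0.86), CASP1 (-0.84), CHS (-0.96) and WRKY70 (-0.97), and brightness as a covariate those of CDKB2;1 (-0.94) and CHS (-0.98). WRKY70 did not pass without water replicate 2 (-0.74) or 3 (-0.98) or 500 mM replicate 1 (-1.04) or 2 (-0.94), BAG6 without water replicate 2 (-0.91) or 500 mM replicate 1 (-0.96), CASP1 without 500 mM replicate 2 (-0.70), CHS without replicate 3 (-0.91), and CASP1, CDKB2;1 and CHS without water replicate 1. P5CDH, KAT1 and CASP1 also lay above background on 1 of the 3 salt arrays, and RVE1, CYP71A13, HSFA6B, LEA7 and PAD3 on 1 of the 3 water arrays.

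**Figure D4:**
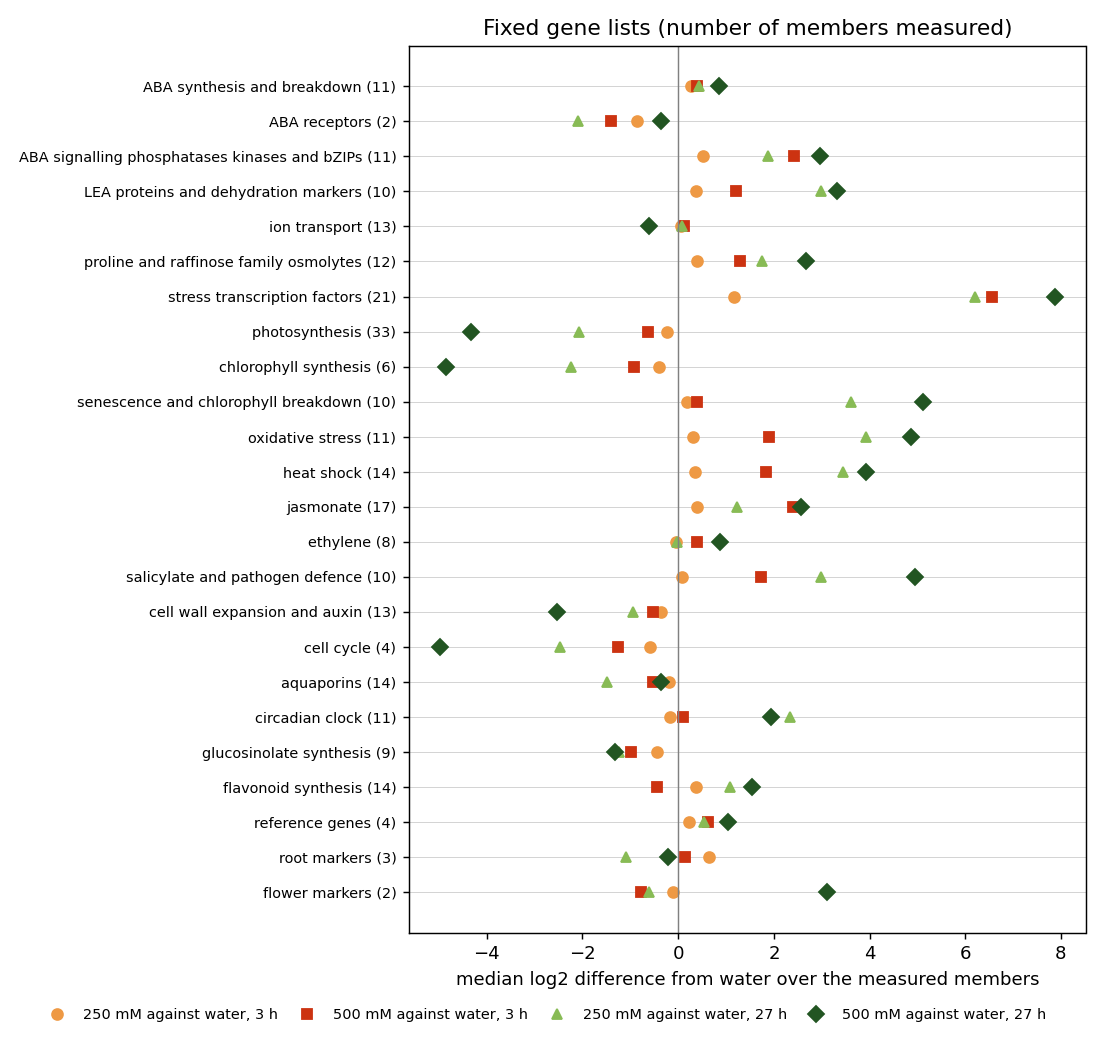
Median log2 difference from water over the measured members of each of the 24 fixed lists, in 4 salt comparisons, with the number of members in brackets. Stress transcription factors run from 1.16 to 7.87 and photosynthesis from -0.23 to -4.33. With scaling to spike-in probes the medians at 250 mM and 27 h lie 1.48 higher, which turns those of the wall and auxin (0.53), glucosinolate (0.24), ethylene (1.46), root (0.38) and flower (0.87) lists upward, and at 500 mM and 27 h it turns those of aquaporins (0.20), abscisic acid receptors (0.22) and root markers (0.34). At 3 h it lowers the medians, those of 250 mM below 0 for all lists but the stress transcription factors (0.40).

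The direct comparison of 500 mM with 250 mM NaCl at 3 h asked what the higher dose added early. The largest rises were AT3G10930 (8.22 ± 0.40), CML38 (8.13 ± 0.35), ERF104 (7.40 ± 0.30), AT5G13210 (7.39) and ERF105 (7.21), and the largest falls AT3G21460 (-2.65 ± 0.43), MYB29 (-2.37 ± 0.26), FLA9 (-2.35), BZIP3 (-2.26) and CYP96A12 (-2.19). Of 21 stress transcription factors 20 were higher at 500 mM (median 4.76, camera adjusted p = 4.21e-20, adjusted p = 0.111 with an estimated correlation). So were 12 of 17 jasmonate genes (adjusted p = 2.37e-09, adjusted p = 0.135 with an estimated correlation), 7 of 10 defence genes (adjusted p = 0.000133, adjusted p = 0.127 with an estimated correlation) and 7 of 11 oxidative stress genes (adjusted p = 5.36e-05, adjusted p = 0.111 with an estimated correlation). NCED3 was higher by 4.06 and RD29B by 2.98. The other 6 lists called, all upward, were abscisic acid synthesis, abscisic acid signalling, embryogenesis and dehydration, proline and raffinose, heat shock and ethylene genes, with an adjusted p from 0.111 to 0.188 with an estimated correlation. The photosynthesis list had a median of -0.43 (adjusted p = 0.0923). Adjusted over the list alone, 2 wall genes and 0 aquaporins were lower against 1 and 1 over all genes, and the other counts were the same.

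Between the doses at 3 h 2455 models were higher at 500 mM and 1567 lower, 61.0% upward with a median of -0.271, and relative to that median 3011 were higher and 668 lower (81.8% upward). Blocked by slide, 4088 models passed, and 3790 within the slide, while 2341 passed with normexp correction (75.2% upward) and 2535 with spike-in scaling (93.3% upward).

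The direct comparison of 500 mM with 250 mM NaCl at 27 h asked what the higher dose added late. The hexose transporter SWEET8 (AT5G40260) was higher by 8.06 ± 0.60, followed by AT1G75030 (7.57), AT3G22620 (6.78), AT1G21525 (6.56) and AT1G69880 (6.41), and PI was higher by 7.26 ± 0.24. The largest falls were AT1G29450 (-5.69 ± 0.32), CYP83A1 (-5.52 ± 0.24), CYP96A12 (-5.38), AT5G23970 (-5.32) and LHCB1.4 (-5.15 ± 0.52). Of 33 photosynthesis genes 31 were lower at 500 mM (median -2.32, camera adjusted p = 4.41e-10, adjusted p = 0.333 with an estimated correlation), as were 5 of 6 chlorophyll synthesis genes (adjusted p = 0.00305, adjusted p = 0.234 with an estimated correlation). Of 10 senescence genes 8 were higher (adjusted p = 0.00265, adjusted p = 0.111 with an estimated correlation), of 21 stress transcription factors 13 (adjusted p = 0.00786, adjusted p = 0.458 with an estimated correlation) and of 17 jasmonate genes 10, or 11 adjusted over the list alone (adjusted p = 0.0187, adjusted p = 0.5 with an estimated correlation). With spike-in scaling 3 of the 10 senescence genes, 4 of the 21 stress transcription factors and 5 of the 17 jasmonate genes were higher, and all 33 photosynthesis and all 6 chlorophyll synthesis genes lower. SOS1 was lower by the test at 500 mM (-2.09 ± 0.34), as were P5CS1 (-1.38 ± 0.22) and RD29B (-1.31 ± 0.43), and PIP2;1 (2.27 ± 0.31), TIP1;1 (2.54 ± 0.33), PYL6 (3.06 ± 0.39) and AOC2 (3.86 ± 0.38) were higher. RD29B no longer passed with array brightness as a covariate (-0.57), without 250 mM replicate 1 (-1.05) or without 500 mM replicate 1 (-1.15). Of 14 aquaporins 6 were higher and 2 lower, with a median of 0.39, but 4 higher and 4 lower and a median of -0.53 with spike-in scaling (camera adjusted p = 0.344).

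Between the doses at 27 h 4566 models were higher at 500 mM and 5339 lower, 46.1% upward. With normexp correction 56.6% of the changed models were higher, with median centring 59.5% and with spike-in scaling 13.8% (1692 higher and 10585 lower). With slide as a block 10009 models passed, and 10023 within the slide. Of the named genes higher at 500 mM, 15 no longer passed with spike-in scaling, RAB18 (0.49, and 0.67 with quantile normalization), ORE1 (0.96) and WRKY6 (0.57) among them.

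The difference between the harvests was tested as the change of each salt effect from 3 h to 27 h. At 250 mM the effect differed for 8642 models, 3897 upward and 4745 downward, and at 500 mM for 11247, 5432 upward and 5815 downward. NCED3 moved up by 3.21 ± 0.39 and RD29B by 3.67 ± 0.61 at 250 mM, whereas at 500 mM their effects changed by 0.05 ± 0.39 and -0.62 ± 0.61, which did not pass. RAB18 moved up by 1.46 ± 0.20 at 250 mM and 2.60 ± 0.20 at 500 mM, and the HKT1 effect differed by -1.64 ± 0.21 and -1.24 ± 0.21, or by 0.60 and -0.24, which did not pass, with spike-in scaling (and -0.87 at 500 mM with normexp correction). With spike-in scaling 17357 models moved upward and 60 downward at 250 mM and 8194 and 1757 at 500 mM, with medians of 2.025 and 1.013 over all models, so the downward moves stated here are against the other transcripts. In the slide-blocked fit 8252 and 10645 models passed. No harvest had its salt and water arrays all on the same slide, so the within-slide values stand with each harvest. In watered plants 3 models were higher and 4 lower at 27 h than at 3 h. The 3 that carry a code were chosen after their values were seen: AT1G75280 (1.12) and AT1G75290 (1.07) were higher and AT3G53980 (-1.44) lower. The spike-in values of this paragraph carry the slide difference of the 3 h water arrays. With spike-in scaling 3 models were higher and 1387 lower, and AT1G75280 (0.39) and AT1G75290 (0.33) did not pass. They did not pass either with a replicate block or without any single water array but the third of 3 h. The count was 1 with slide as a block. It was 643 without the third water array of 3 h, 544 without the first of 27 h, 3 and 2 without the other water arrays of 3 h and 4 and 2 without those of 27 h. Within the slide that held a water array of each harvest, 1 array against 1 with the spread taken from the salt groups alone, it was 0 by limma, with 2128 models at an unadjusted p under 0.05.

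The overlaps asked which responses recurred. Of the 127 models that rose at 250 mM and 3 h, 121 also rose at 500 mM and 3 h, against 14.9 for independent lists, and of the 40 that fell 27 also fell, against 6, while 4 rose. At 27 h 3581 models rose at both doses, against 1072.8, and 4577 fell at both, against 2068.5. Across harvests, 118 of the 127 early rises at 250 mM recurred at 27 h, against 22.5, and 19 of the 40 early falls, against 10.4, while 0 of the rises and 8 of the falls were called the other way. At 500 mM 2409 rises and 2459 falls recurred, against 710.4 and 1189.7, and 71 and 179 went the other way. The early rises at 500 mM and the late rises at 250 mM shared 2299 models, against 484.9. The doses share their water arrays within a harvest, so a part of the excess within a harvest can come from that sharing. In 20 simulated data sets with unchanged salt groups and the shared water arrays the overlap was 0 at both harvests, but few or no genes are expected to pass in unchanged groups, so this gives no chance value for lists of the observed size. The water arrays were therefore divided, 1 array to one dose and 2 to the other in each of 6 ways, with the lone array taken to vary like the others, a test chosen after the data were seen. At 3 h 19 to 124 models then rose at both doses, against 2.6 to 18 for independent lists, and 1 to 42 fell at both, against 0.5 to 27.8, with 0 to 40 in opposite directions. At 27 h 3164 to 3636 rose at both, against 1014.9 to 1174.9, and 4076 to 4820 fell at both, against 1793.7 to 2381.6, with 46 to 528 in opposite directions. Once slide was a block, the overlap of the doses at 3 h was 58 models in both directions together, and that of the harvests at 250 mM was 53.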

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

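The tests on slide, array brightness, exchanged arrays, array scaling and clock time, and those on the spike-in probes, were chosen after the results were seen, while the splits of the arrays and the lists matched on level were planned.

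The early genes at 250 mM stand on water arrays of which 2 lay on a slide with no salt array. Of the 127 genes higher at 250 mM and 3 h, 92.9% were also called higher at 27 h on other arrays, where 17.7% of all models were. This argues against the slide of the water arrays as the whole cause. With array brightness as a covariate 96.1% stayed called, which argues against brightness. With scaling to spike-in probes the median of these genes was 0.78 and 16 stayed called, so array scaling may account for a part. That scaling carries a slide difference, since the spike-in signal was 9.88 and 9.80 on the 2 water arrays alone on a slide and 11.62 on the third. On the slide of the third the 75th percentile over the spike-ins was -1.46 in water and -1.51, -1.60 and -1.93 at 250 mM. Scaling and slide cannot be told apart here. Of the 40 genes lower, 95% stayed called with brightness as a covariate and the 75th percentile over the spike-ins differed from water by -0.76, the wrong way to give falls, which argues against brightness and array scaling. Of these 47.5% were called lower at 27 h against 25.9% of all models. Their median was -1.12 with slide as a block against -1.35, but selection on the same arrays alone can give that drop. A slide difference cannot be told apart from salt. An early salt response stays open for both.

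The photosynthesis list was lower at 27 h at both doses. With scaling to spike-in probes its median was -3.77 at 500 mM, which argues against array scaling as the whole cause there, and -0.60 at 250 mM, where a part of the -2.08 may come from scaling and stays open. Of 10000 random lists matched on level in water 0% were as low. Theirs centred on -1.52 at 250 mM and -1.46 at 500 mM (lowest -1.91 and -3.71), so gene brightness may give a part, not all. All 33 genes fell at 500 mM, but a fall with salt beyond other genes is a hypothesis (camera adjusted p = 0.333 with an estimated correlation).

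The morning clock genes, 4 of 4, were called higher at 27 h at both doses. A harvest of the salt plants at another clock time would raise morning genes and lower evening genes, but at 500 mM 4 of 6 evening genes were called higher and 1 lower, or 4 and 2 of 7 with GRP7, which had been left out, and this argues against clock time as the whole cause there. At 250 mM 3 of 6 were called higher and 1 lower, or 3 and 2 of 7 with GRP7, and clock time stays open at both doses. The 75th percentile over the spike-ins stood 1.48 higher than in water at 250 mM and 0.56 higher at 500 mM, so scaling to it lowered the differences, which argues against array scaling as the cause of rises of at least 3.92 and 1.90. A mix of harvest time and salt may still contribute and was not tested.

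For the comparisons of 3 arrays with 3 the 10 splits are too few for a share under 0.05. The real count and the highest of the other splits, in limma fits, were 167 and 0 at 250 mM and 3 h, 6228 and 7 at 500 mM and 3 h, 10202 and 0 at 250 mM and 27 h, 14057 and 0 at 500 mM and 27 h, 4022 and 788 between doses at 3 h, and 9905 and 0 between doses at 27 h, each real split being 1 of 10 with as many. Between harvests in watered plants 2 of 10 splits gave as many as the real 7, and the highest, 1995, set the 2 water arrays of 3 h that share a slide, with the first of 27 h, against the rest, which points to a structure of the samples. That split exchanges the third water array of 3 h and the first of 27 h. On the second principal component they lay at -9.5 and -50.5, while the other water arrays lay at -47.8 and -60.6 for 3 h and at 6.9 and -3.7 for 27 h, and the count was 643 and 544 without 1 of them. The 2 arrays may have been exchanged, or may stand apart for another reason such as brightness, since the exchanged groups gave 0 models by limma with brightness as a covariate (1455 at an unadjusted p under 0.05), and the data do not decide between these. For the change of the salt effect between harvests 7 of 100 splits at 250 mM gave at least the real 8642 (highest other 11631) and 11 of 100 at 500 mM at least the real 11247 (highest other 14167), and all 7 and all 11 kept the salt and water groups of 27 h whole. As 8 and 11 of the 100 splits did so and keep the large effect of 27 h, this count could hardly have excluded chance and says nothing on it. The highest count among the other splits was 2 and 532.

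The salt effect differed between harvests, by a test of the difference itself, for 8642 models at 250 mM and 11247 at 500 mM, among them 175 and 166 members of the lists. At 250 mM the largest upward changes were CML38 (8.79), AT1G68765 (8.27), ERF104 (8.23), SYP122 (7.85) and AT1G76600 (7.73). The largest downward changes at 250 mM were XTH31 (-5.19), AT1G19960 (-5.12), EXPB1 (-5.10), AT3G55240 (-4.73) and ECS1 (-4.55). At 500 mM the largest upward changes were AT5G64790 (9.36), AT5G55150 (8.19), AT1G02310 (7.83), AT1G75030 (7.82) and AT1G21525 (7.64). The largest downward changes at 500 mM were LHCB1.4 (-8.05), AT1G29450 (-6.84), CYP83A1 (-6.76), LTL1 (-6.70) and PSAF (-6.27). In the spike-in probes, which the comparisons do not use, the 75th percentile stood 1.48 log2 units higher over the spike-ins at 250 mM than in water at 27 h, with all 3 salt arrays above all 3 water arrays.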

How the results depend on the processing

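Runs chosen after the data were seen are named with the processing. Water arrays lay in column 4 and salt arrays in columns 1 to 3, 250 mM in row 1 and 500 mM in row 2. No fit by slide can separate treatment or dose from this slide position. Signal over background limits the dim probes, and scan date was not run as a block because it equals slide. The count at 500 mM and 27 h stayed within 1.5 times under every alternative run. Of 714 gene values named in the text 672 kept direction and side of the threshold with slide as a block, 681 with normexp, 687 with quantile normalization, 691 with median centring, 709 with a replicate block, 680 with brightness as a covariate and 602 with spike-in scaling. Between doses at 3 h the own number was the best match for 4 of 6 arrays (correlations 0.48, -0.05 and 0.58), a hint that number and place on the slide go together, and the replicate block gave 3995 models there against 4022. In the other comparisons it was the best match for 0 to 3 of 6. Of 144 list tests 131 were the same with slide as a block (the 13 lost calls are named with their comparisons), 137 with quantile normalization, 131 with spike-in scaling and 99 with fry, while with an estimated correlation 0 of the 72 calls passed by camera, with 44 tests at an unadjusted p under 0.05.

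For the changed values below the cause was not tested, except where fewer arrays or another threshold make it plain. The 167 models at 250 mM and 3 h became 45 with normexp, 109 with no filter, 101 with a filter on all 18 arrays, 63 with slide as a fixed and 71 as a random block, 1 within slide 1 (1 water array), 10 on the compared arrays alone, 1195 with array weights (26.1% higher), 58 at an adjusted p under 0.01, 28 without the 2 water arrays of slide 3, 274 with brightness as a covariate, 303 with spike-in scaling (5.28% higher) and 685 with the 2 water arrays of slide 1 exchanged (144 of them shared). The 7 in watered plants became 4 with normexp, 27 with quantile normalization, 2 with no filter, 1 with slide as a fixed or random block, 2 with a replicate block, 0 within slide 1 (1 array against 1, 2128 at an unadjusted p under 0.05 in limma), 0 on the compared arrays alone (1724 so), 2491 with array weights, 11 with no fold threshold, 2 at an adjusted p under 0.01, 2 without the 2 water arrays of slide 3 15 with brightness as a covariate, 1390 with spike-in scaling, 1995 with the 2 water arrays of slide 1 exchanged, and 0 with that exchange and brightness as a covariate (1455 at an unadjusted p under 0.05 in limma). With spike-in scaling 9474 models changed at 500 mM and 3 h and the 250 mM effect changed between harvests for 17417. With normexp 3850 models changed at 500 mM and 3 h and 2341 between doses at 3 h, which was 2537 with a filter on all 18 arrays and 2535 with spike-in scaling. With no fold threshold the counts were 12932 at 500 mM and 3 h, 15820 at 250 mM and 27 h, 10077 between doses at 3 h and 15891 between doses at 27 h, and the overlaps were 12534 for the doses at 27 h, 207 for the harvests at 250 mM and 9998 for the harvests at 500 mM. With slide as a fixed block the overlap of the doses at 3 h was 58 and that of the harvests at 250 mM was 53.

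Leaving out each array in turn gave 70 to 416 models at 250 mM and 3 h. It gave 2 to 643 in watered plants, by array as given with these comparisons. The ranges were 5593 to 7481 at 500 mM and 3 h, 9699 to 10547 at 250 mM and 27 h, 13943 to 14234 at 500 mM and 27 h, 3619 to 4741 and 9381 to 10079 between doses, 7965 to 9198 and 10906 to 11799 for the changes between harvests, and 69 to 75 list calls.

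Direction turned with normexp for RVE1 at 500 mM and 3 h (-0.02) and CYCB1;1 between doses at 27 h (0.18), and with quantile normalization for GRP7 at 250 mM and 27 h (0.16). With spike-in scaling it turned at 250 mM and 27 h for AHG1 (0.30), AOC2 (0.18), CBL10 (0.30), EXPA1 (0.21), GRP7 (0.37), ICS1 (0.17), MYB29 (0.06), PI (1.38), PIP2;2 (0.10), PYL1 (1.04), SEP3 (0.37), SUR1 (0.24) and TIP2;3 (0.38), and for the change of the HKT1 effect at 250 mM between harvests (0.60).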

Other observations

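Some gene models appeared, well above background on all 3 salt arrays and on none of the 3 water arrays. At 250 and 500 mM these were 20 and 370 at 3 h and 669 and 1200 at 27 h. Called higher were 12, 341, 645 and 1177 of them. In the same order 9, 29, 73 and 741 did the reverse, and 0, 29, 72 and 730 of these were called lower. No thaliana code was carried by 45%, 57.6%, 63.4% and 66.5% of those that appeared and by 100%, 65.5%, 63.0% and 57.1% of the reverse. Among all models tested the share was 54.2%. Among named genes that appeared were the ethylene synthesis gene ACS7, at least 826-fold higher at 500 mM and 27 h, the senescence gene SAG13, at least 216-fold higher, and the immunophilin gene ROF2, at least 127-fold higher. ALD1, which acts in systemic resistance, was at least 32.4-fold higher at 500 mM than at 250 mM at 27 h.

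For 348 genes with 2 probes the probes differed by a median of 0.06 on the log2 scale in both comparisons of 500 mM with water. Of the variance within groups 42.8% lay along a single axis. Furthest out on it were the first water array of 27 h (-63.4), the third of 3 h (46.2), the third (-42.7) and first (41.1) 500 mM arrays of 3 h and the second water array of 27 h (39.6), and their brightness deviated from the group mean by -0.92, 0.65, -0.49, 0.56 and 0.65 log2 units. The 75th percentile over the spike-ins was -0.92 ± 0.53 in water at 3 h, -1.68 ± 0.22 at 250 mM, -1.36 ± 0.64 at 500 mM, and at 27 h -1.66 ± 0.75 in water, -0.18 ± 0.05 at 250 mM and -1.09 ± 0.24 at 500 mM (SD, n = 3).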
